A study of Homo sapiens with 18 samples.

How the data were processed

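The samples were primary human mammary epithelial cells (HMECs) at passage 5, cultured in 6 conditions with 3 libraries each. The conditions were untreated control, D2HG, L2HG, both compounds together (D2HG+L2HG), L2HG with vitamin C given as A2P (L2HG+vitC), and L2HG followed by its withdrawal. D2HG and L2HG are the D and L enantiomers of the metabolite 2-hydroxyglutarate. Per the labels, total RNA (500 ng per library, quality scores 9.2 to 10.0) was depleted of ribosomal RNA and sequenced as single reads of 50 bases. Doses and exposure times are not given in the sources used here, so no comparison can be said to be at matched doses or times. No condition received vitamin C without L2HG.

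The deposited values were raw counts per gene symbol, as the authors made them from the reads, and a check found whole numbers in every library. The submitters' processing notes name FastQC 0.11.9, MultiQC 0.8, cutadapt 1.18, STAR 2.7.5a, DESeq2 1.26.0 and the human build GRCh38 (hg38). The gene annotation, the counting program and the strand setting are not given in the sources used here. The table held 29744 symbols, of which 25001 (84.1%) matched a symbol or synonym in the RefSeq annotation of GRCh38 that was used to look up positions. Some symbols are older names and are printed as they stand in the table (CTGF, IL8, C12orf5 and the HIST1 histone names). Library totals ran from 13019540 to 16580685 counts. The 10 most abundant genes took 15.94% to 23.15% of a library, and the symbols RNR1 and RNR2 together took 9.16% to 14.66%. Reads are not separate molecules, so counting intervals cover counting error only.

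Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 14860. Counts were scaled by TMM (factors 0.933 to 1.07), and 1 edgeR 4.0.16 quasi-likelihood model with robust dispersion was fitted to all 18 libraries in R 4.3.3, with 1 mean per group and 12 residual degrees of freedom. Its biological coefficient of variation was 8.85%. The model gives each gene 1 dispersion for all groups, but the groups differed in spread. Between 2 libraries of a group, chi-square over genes per degree of freedom was 1.955 to 2.166 after withdrawal and 2.44 to 3.95 with L2HG+vitC. It was 4.11 to 9.53 with D2HG, 10.7 to 22.5 in the controls, 8.54 to 22.7 with L2HG and 4.415 to 30.42 with both compounds. The shared dispersion can thus be too small for groups with more spread and too large for others. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, 2-sided, in each of 10 comparisons. Standard errors (SE) of log2 changes were taken from the change and its F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. Principal components and list scores used log2 CPM with a prior count of 2. Adjusted p-values of genes come from edgeR over all genes tested, or from DESeq2 where it is named. They measure only the spread between these libraries, which may be technical. The labels do not say whether the 3 libraries of a group come from separate cultures. Camera p-values of gene lists compare the genes of a list with all other genes and are adjusted over the lists. They also rest on the correlation set or estimated between genes, and do not measure the spread between libraries alone.

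Before the data were examined, 31 gene lists with 864 symbols were written, of which 851 were in the table. The 26 lists with at least 5 tested genes were used: basal and myoepithelial, luminal, keratinocyte differentiation, mesenchymal, collagens and their hydroxylases, TET and histone demethylases, hydroxyglutarate and citric acid cycle metabolism, HIF targets, G2/M, G1/S, replication-dependent histones, homologous recombination repair, p53 targets, senescence-associated secretory factors, NF-kB targets, interferon response, NRF2 targets, ATF4 and amino acid response, endoplasmic reticulum stress, cholesterol synthesis, fatty acid synthesis, nuclear-encoded respiratory chain, ribosomal proteins, TGF-beta and YAP targets, immediate early genes and fibroblast markers. Endothelial, immune and adipocyte markers (2, 4 and 2 tested genes), methylation-silenced germline genes (3) and mitochondrially encoded genes (0) were too few and were not used. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Camera with an estimated correlation, fry and a limma fit of the list score with its 95% interval were run beside it. The counts of called members are also given as adjusted over the list alone.

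Named genes followed a rule written beforehand: called, at least 1 CPM on average, all 3 libraries of one group above all 3 of the other, and among the 8 largest rises and 8 largest falls in the comparisons of D2HG, L2HG and D2HG+L2HG with control, or the 4 and 4 largest in the other 7. For a described list, up to 4 members with the smallest p were eligible. D2HGDH, TET1, TET2, TET3, KRT5, KRT14, KRT8, KRT18, KRT19, TP63 and VIM are given whether called or not. Some genes that the rule names are not reported here.

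The procedure was tested on simulated data in which each gene was drawn independently from its mean level and fitted dispersion. With 3 libraries per group, 59.7% to 64.2% of genes changed 1.5-fold, 82.1% to 85.1% of genes changed 2-fold and 95.5% of genes changed 4-fold were called, and 3.3% to 3.68% of the calls were unchanged genes. A changed list had camera p of 4.84e-48 and 1.93e-35, and an unchanged list 0.993 and 0.663. Since the simulated genes were independent, this does not test camera on lists whose genes are correlated. All groups were drawn with the same dispersion per gene, so the shares of calls do not cover groups of unequal spread. The alternatives tried were RLE factors, no filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, the replicate number as a block, a fit of the compared groups alone, leaving out each library in turn, and, chosen after the data were seen, leaving out 3 libraries together. A scaling on spike-in counts was not run. Figures were drawn with matplotlib 3.10.9.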

Results

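RNA from 18 libraries of primary human mammary epithelial cells gave 14860 genes for testing. Principal component 1 held 42.6% of the variance and separated the control and withdrawal libraries from those with D2HG, L2HG or both, with the L2HG+vitC libraries in between. Principal component 2 held 11.4%. Control replicate 2 and D2HG+L2HG replicate 1 stood apart from the other libraries of their groups on component 2, and L2HG replicate 3 stood apart from its group on both. The nuclear RNA MALAT1 took 0.933% to 1.20% of the counts in the controls and 1.77% to 3.15% in the treated and withdrawn libraries, except D2HG+L2HG replicate 1, whose share lay within the control range.

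**Figure D1:**
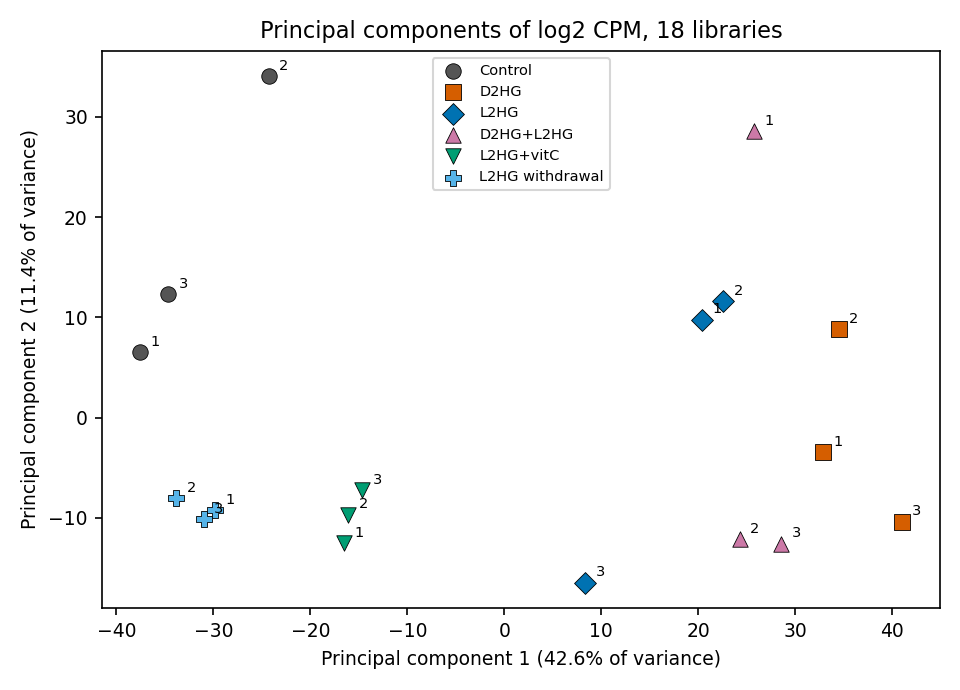
Principal components 1 (x axis, 42.6% of the variance) and 2 (y axis, 11.4%) of log2 CPM, 1 point per library with its replicate number and colour and shape by group. The withdrawal libraries lie beside the controls on component 1 and the L2HG+vitC libraries between them and the libraries with D2HG, L2HG or both.

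With D2HG, genes of epidermal differentiation rose and genes of the cell cycle fell. The largest rise was in DHRS9, a retinol dehydrogenase of the short-chain family, from 0.232 ± 0.079 CPM in the controls to 20.7 ± 2.93 CPM (84.5-fold, SE 0.29 on the log2 scale, adjusted p = 2.56e-13). In the GRCh38 RefSeq annotation it lies on chromosome 2 from 169067077 to 169096167. The cadherin CDH16 (chromosome 16, 66908122 to 66918885) rose 43.1-fold from 0.156 ± 0.137 CPM, the phospholipase PLA2G4E 18.3-fold, and the growth factor BMP6 (chromosome 6, 7726099 to 7881728) 17.3-fold, from 1.20 ± 0.509 to 21.3 ± 3.26 CPM. TMOD1, which caps actin filaments, rose 17.8-fold to 2.08 ± 0.956 CPM, the chemokine PPBP 15.2-fold, the adhesion gene IGSF9B 14.1-fold and the nucleoside transporter SLC28A3 13.4-fold, each with an adjusted p of 4.13e-06 or less. The largest falls were in ACSS1, a mitochondrial acetyl-CoA synthetase (chromosome 20, 25006237 to 25058139), 6.83-fold to 0.378 ± 0.224 CPM (log2 change -2.77, SE 0.37, adjusted p = 2.31e-06), and in the adhesion gene SDK1 (-2.53, SE 0.30). TOX2 (-2.33), the double-stranded RNA sensor TLR3 (-2.31), the interferon-induced ligase HERC5 (-2.31), the surface glycoprotein THY1 (-2.16) and the histone genes HIST1H3J (-2.15) and HIST1H4I (-2.10) followed, with adjusted p of 0.000333 or less. All 3 D2HG libraries lay on the stated side of all 3 controls for each of these 16 genes.

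In the keratinocyte differentiation list, 30 of 33 tested genes rose with D2HG and 0 fell (30 adjusted over the list alone), with a median log2 change of 2.02 (camera adjusted p = 3.42e-21, and adjusted p = 0.0542 with an estimated correlation). PI3, the antiprotease elafin, rose from 16.7 ± 4.48 to 182 ± 14 CPM (log2 change 3.44, SE 0.20, adjusted p = 1.2e-09), the desmosomal cadherin DSC1 by 2.65 (SE 0.24), the cornified envelope gene SPRR2D by 2.80 (SE 0.29) and filaggrin, FLG, by 1.55 (SE 0.16). SPRR2 genes resemble each other, so short reads may be shared between them and the level of a single member is uncertain. The score of this list, its mean log2 CPM, was 3.44 ± 0.343 in the controls (3.07 to 3.75 by library), 5.45 ± 0.0743 with D2HG, 5.13 ± 0.511 with L2HG, 4.84 ± 0.279 with both, 4.54 ± 0.0748 with L2HG+vitC and 3.97 ± 0.0704 after withdrawal (SD, 3 libraries each).

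All 30 G2/M genes fell with D2HG (30 adjusted over the list alone, median -1.06, camera adjusted p = 1.17e-40, and adjusted p = 0.0174 with an estimated correlation). The mitotic kinesin KIF20A fell from 72.2 ± 2.72 to 29.9 ± 1.78 CPM (log2 change -1.27, SE 0.077), KIF2C by 1.15, DLGAP5 by 1.01 and cyclin A2, CCNA2, by 1.07. In the G1/S list 28 of 30 genes fell (29 adjusted over the list alone, median -0.95, camera adjusted p = 1.52e-25, and adjusted p = 0.0439 with an estimated correlation), among them TYMS (-1.24, SE 0.094), PCNA (-1.06) and MCM7 (-1.09). All 37 replication-dependent histone genes fell (37 adjusted over the list alone, median -1.55, camera adjusted p = 2.99e-34, and adjusted p = 0.0542 with an estimated correlation), including HIST1H3A (-1.82, SE 0.14) and HIST1H1E (-1.09, SE 0.097). Their near-identical sequences make the level of any single histone gene uncertain. Homologous recombination repair genes fell in 20 of 26 cases and rose in 0 (22 and 1 adjusted over the list alone, median -0.72, camera adjusted p = 8.71e-13, and adjusted p = 0.0439 with an estimated correlation), with RAD51C at -1.32 (SE 0.11), FANCI at -0.98, EXO1 at -1.41 and BLM at -1.13.

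Of 27 senescence-associated secretory genes, 15 rose and 4 fell with D2HG (median 0.68, camera adjusted p = 1.1e-08, and adjusted p = 0.0386 with an estimated correlation). The matrix protease MMP10 went from 20.7 ± 5.56 to 140 ± 3.56 CPM (log2 change 2.75, SE 0.11, adjusted p = 1.19e-13), MMP1 from 37.6 ± 15.3 to 338 ± 10.9 CPM, SERPINB2 rose from 35.3 ± 11.6 to 229 ± 17.4 CPM and TIMP2 by 1.98 (SE 0.16). Immediate early genes rose in 15 of 26 cases and fell in 2 (camera adjusted p = 2.58e-06, and adjusted p = 0.0441 with an estimated correlation), with SPRY2 at 1.61 (SE 0.084) and JUNB at 1.08. HIF targets rose in 15 of 35 cases and fell in 2 (15 and 3 adjusted over the list alone, median 0.19, camera adjusted p = 0.00063, and adjusted p = 0.0302 with an estimated correlation), with NDRG1, which hypoxia induces, at 1.74 (SE 0.15) and the glucose transporter SLC2A1 at 586 ± 24.8 against 258 ± 51.8 CPM. Endoplasmic reticulum stress genes fell in 12 of 23 cases (median -0.22, camera adjusted p = 0.00158, and adjusted p = 0.0557 with an estimated correlation). p53 targets fell in 13 of 27 and rose in 2 (camera adjusted p = 0.0164, 0.0741 without control replicate 2, and adjusted p = 0.171 with an estimated correlation). TGF-beta and YAP targets fell in 10 of 24 and rose in 4 (camera adjusted p = 0.00604, and adjusted p = 0.514 with an estimated correlation). The edgeR test called 5647 genes in D2HG against control, 2717 higher and 2930 lower, of which 1292 changed at least 2-fold. Neither the leave-out fits nor the other settings moved this count by over 1.5 times.

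With L2HG, CDH16 rose 19.8-fold (log2 change 4.31, SE 0.51, adjusted p = 1.28e-06), KRT24, a keratin of differentiated epidermis (chromosome 17, 40697991 to 40703752), 16.7-fold from 0.879 ± 0.127 to 14.9 ± 4.78 CPM, and DHRS9 16.6-fold to 4.06 ± 1.06 CPM. CYP4F22, a fatty acid hydroxylase of skin barrier lipids, rose 14.9-fold to 2.04 ± 1.20 CPM, PLA2G4E 10.6-fold, LEMD1 9.47-fold, the calcium-binding CALB1 9.23-fold and the amino acid transporter SLC6A14 8.4-fold, from 5.16 ± 1.57 to 43.8 ± 7.81 CPM. Falls were largest in cytoglobin, CYGB (log2 change -2.48, SE 0.34, adjusted p = 8.41e-06), THY1 (-2.14), the muscle-atrophy ligase FBXO32 (-2.11, SE 0.15), HERC5 (-1.88), MOXD1 (-1.83), ACSS1 (-1.80), the cytokine receptor IL7R (-1.77) and DHRS3 (-1.75, SE 0.17), a retinaldehyde reductase that went from 13.2 ± 2.93 to 3.93 ± 0.665 CPM. For these 16 genes all 3 L2HG libraries lay on 1 side of all 3 controls.

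Keratinocyte differentiation genes rose in 29 of 33 cases with L2HG and fell in 0 (30 and 0 adjusted over the list alone, median 1.78, camera adjusted p = 2.85e-24, and adjusted p = 0.16 with an estimated correlation). PI3 rose by 2.63 on the log2 scale (SE 0.20) and KLK7, a protease of skin shedding, by 1.92 (SE 0.20). All 30 G2/M genes fell (30 adjusted over the list alone, median -0.67, camera adjusted p = 2.6e-30, and adjusted p = 0.0585 with an estimated correlation), with KIF20A at -0.77 (SE 0.074) and TPX2 at -0.66 (SE 0.075). G1/S genes fell in 26 of 30 cases (27 adjusted over the list alone, median -0.57, camera adjusted p = 7.77e-17, and adjusted p = 0.166 with an estimated correlation), with PCNA at -0.81. Histone genes fell in 36 of 37 (37 adjusted over the list alone, median -0.93, camera adjusted p = 1.57e-25, and adjusted p = 0.166 with an estimated correlation). Homologous recombination genes fell in 19 of 26 cases and rose in 1 (camera adjusted p = 3.68e-07, and adjusted p = 0.166 with an estimated correlation), with RAD51C at -0.77.

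Basal and myoepithelial genes rose in 11 of 25 cases and fell in 5 with L2HG (median 0.34, camera adjusted p = 0.014, and adjusted p = 0.21 with an estimated correlation). COL17A1, a hemidesmosomal collagen, rose from 1823 ± 181 to 3445 ± 162 CPM, while caveolin, CAV1, fell by 0.52 (SE 0.067). The list was not called without control replicate 1 (adjusted p = 0.142). Senescence-associated secretory genes rose in 9 of 27 cases and fell in 3 (camera adjusted p = 0.00543 upward, and adjusted p = 0.26 with an estimated correlation), although their median was -0.00464 and their mean 0.22. The call was lost with no filter on low counts (adjusted p = 0.0833). MMP10 rose by 2.09 (SE 0.11) and SERPINB2 by 2.39 (SE 0.14). Immediate early genes rose in 10 of 26 cases and fell in 2 (camera adjusted p = 0.0135, 0.0584 without L2HG replicate 3, and adjusted p = 0.26 with an estimated correlation). Endoplasmic reticulum stress genes fell in 11 of 23 (camera adjusted p = 0.00198, and adjusted p = 0.16 with an estimated correlation). TGF-beta and YAP targets fell in 11 of 24 and rose in 4 (camera adjusted p = 0.00279, and adjusted p = 0.538 with an estimated correlation). HIF targets rose in 9 of 35 and fell in 3, and that list was not called (camera adjusted p = 0.164). The edgeR test called 4177 genes in L2HG against control, 1988 higher and 2189 lower, 742 of them at least 2-fold. A fit of these 6 libraries alone called 2550.

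**Figure D2:**
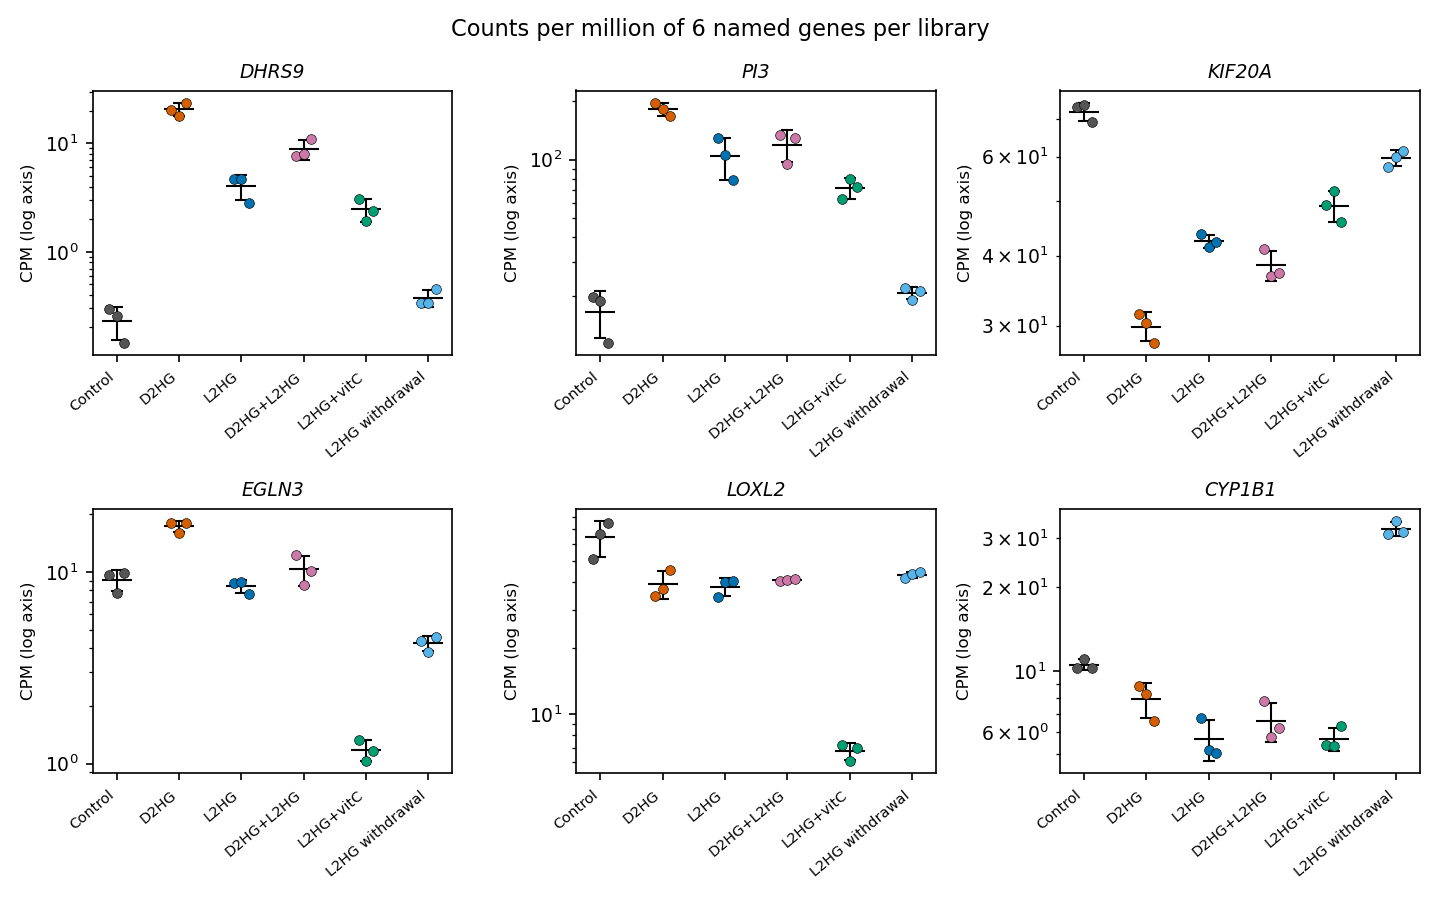
CPM (y axis, log scale) of DHRS9, PI3, KIF20A, EGLN3, LOXL2 and CYP1B1 in each of 6 groups (x axis), 1 point per library, with a dash at the mean and bars of 1 SD over 3 libraries. DHRS9 stands at 20.7 CPM with D2HG and 4.06 with L2HG, LOXL2 at 6.76 with L2HG+vitC and CYP1B1 at 32.5 after withdrawal.

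The enantiomers were compared directly, with the reservation that their doses and times are not given in the sources used here. Over 6474 genes called with either compound, the median size of the log2 change against control was 0.503 with D2HG and 0.379 with L2HG. The direct test of L2HG against D2HG called 1280 genes, 525 higher and 755 lower with L2HG, 110 of them at least 2-fold. Of these, 1178 were among the 6474, with the larger change with D2HG in 1020 and with L2HG in 158. DHRS9 was lower with L2HG than with D2HG by a log2 difference of -2.35 (95% interval -2.73 to -1.96, adjusted p = 5.21e-08), BMP6 by -1.79 (-2.14 to -1.43), the integrin gene ITGB3 by -2.01 (-2.76 to -1.27) and GPNMB by -1.80 (-2.33 to -1.27). Higher with L2HG were the actin-binding TAGLN, 20.9 ± 0.514 against 6.87 ± 0.712 CPM (log2 difference 1.60, interval 1.30 to 1.90, adjusted p = 5.72e-07), PYCR1 of proline synthesis (1.43, 1.06 to 1.81), SULT4A1 (interval 0.793 to 2.20) and NRSN2 (1.48, 0.52 to 2.44). The call of NRSN2 was lost in 7 other fits (up to adjusted p = 0.201, without D2HG replicate 2) and that of SULT4A1 without D2HG replicate 1 (adjusted p = 0.0532).

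By list, L2HG cells held more cell cycle RNA than D2HG cells. G2/M genes were higher in 16 of 30 cases (25 adjusted over the list alone, median 0.35, camera adjusted p = 1.06e-17, and adjusted p = 0.0582 with an estimated correlation), with KIF20A at 0.50 (SE 0.078). G1/S genes were higher in 14 of 30 (24 adjusted over the list alone, camera adjusted p = 1.34e-14, and adjusted p = 0.121 with an estimated correlation). Histones were higher in 14 of 37 (28 adjusted over the list alone, median 0.51, camera adjusted p = 4.69e-16, and adjusted p = 0.215 with an estimated correlation). Homologous recombination genes were higher in 10 of 26 (17 adjusted over the list alone, camera adjusted p = 1.04e-09, and adjusted p = 0.0772 with an estimated correlation). Lower with L2HG were senescence-associated secretory genes, 12 of 27 with 2 higher (median -0.49, camera adjusted p = 5.63e-12, and adjusted p = 0.0218 with an estimated correlation), among them IL1B at 34.8 ± 1.02 against 85.4 ± 3.66 CPM (log2 difference -1.29, SE 0.08). HIF targets were lower in 11 of 35 (camera adjusted p = 7.53e-06, and adjusted p = 0.00818 with an estimated correlation), with HK2 at -0.77 (SE 0.088) and EGLN3 at -1.03 (SE 0.13). Immediate early genes were lower in 8 of 26 with 1 higher (camera adjusted p = 1.59e-07, and adjusted p = 0.0393 with an estimated correlation). NF-kB targets were lower in 5 of 26 (9 adjusted over the list alone, camera adjusted p = 1.96e-05, and adjusted p = 0.0458 with an estimated correlation). Luminal genes were lower in 5 of 25 (camera adjusted p = 0.000626, and adjusted p = 0.121 with an estimated correlation), led by EPCAM at -0.84 (SE 0.11).

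The keratinocyte differentiation list differed between the enantiomers by a score of -0.317 (L2HG minus D2HG, 95% interval -0.765 to 0.131). Only 4 of its 33 genes were lower with L2HG, DSC1, FLG, PI3 and IVL, and its camera call (adjusted p = 0.00226, and adjusted p = 0.504 with an estimated correlation) was lost without L2HG replicate 3 (adjusted p = 0.799). For the basal list the score differed by 0.0267 (-0.0671 to 0.121), for TET and histone demethylases by -0.0425 (-0.108 to 0.0229) and for hydroxyglutarate and citric acid cycle genes by -0.046 (-0.153 to 0.061), and none of these lists was called (camera adjusted p = 0.705, 0.241 and 0.3). Without D2HG replicate 1, D2HG replicate 3 or L2HG replicate 1, the direct comparison called 797, 677 or 757 genes. It called 2358 without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1 together. Of its calls, 37.1% to 46.4% were higher with L2HG when 1 library was left out, and 51% without those 3 together.

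**Figure D3:**
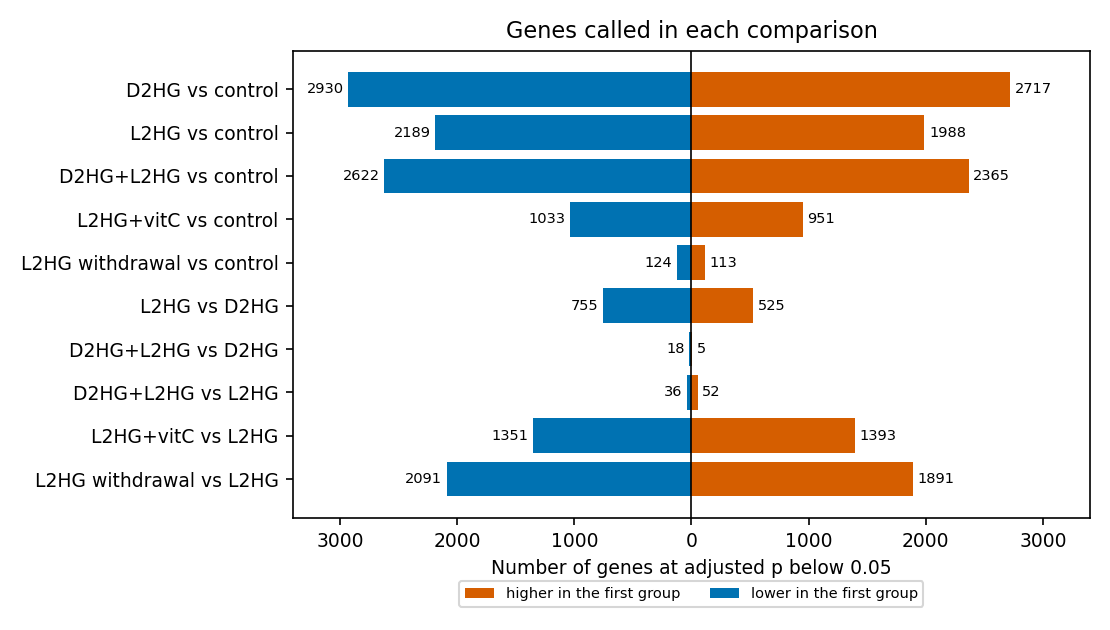
Number of genes at an adjusted p below 0.05 (x axis) in each of 10 comparisons (y axis), higher in the first group to the right and lower to the left of 0. The counts are 2717 and 2930 for D2HG against control, and 5 and 18 for D2HG+L2HG against D2HG.

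With both compounds together, DHRS9 rose 36.4-fold to 8.95 ± 1.87 CPM (log2 change 5.19, SE 0.31, adjusted p = 4.11e-11), CDH16 31.7-fold, BMP6 11.9-fold, IGSF9B 10.2-fold, PPBP 9.92-fold, LEMD1 9.09-fold, PLA2G4E 8.75-fold and the G protein gene GNAO1 8.69-fold. The falls were led by SDK1 (log2 change -2.14, SE 0.28, adjusted p = 3.42e-06), ACSS1 (-2.06), the matricellular CTGF (-2.03, SE 0.24), the retinoic acid receptor RARB (-1.92), HIST1H3J (-1.90), TOX2 (-1.87), TGFB2 (-1.86, from 65.7 ± 20 to 18.1 ± 0.303 CPM) and CYGB (-1.85). For each of them the 3 treated libraries lay on 1 side of the 3 controls.

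Keratinocyte differentiation genes rose in 26 of 33 cases with both compounds (27 adjusted over the list alone, median 1.40, camera adjusted p = 1e-14, and adjusted p = 0.128 with an estimated correlation), with KRT16 at 1578 ± 296 against 315 ± 94.2 CPM. All 30 G2/M genes fell (median -0.80, camera adjusted p = 3.9e-32, and adjusted p = 0.0546 with an estimated correlation). All 37 histone genes fell (median -1.32, camera adjusted p = 1.01e-34, and adjusted p = 0.0588 with an estimated correlation). So did 28 of 30 G1/S genes (camera adjusted p = 2.36e-25, and adjusted p = 0.056 with an estimated correlation). Homologous recombination genes fell in 21 of 26 cases and rose in 1 (camera adjusted p = 1.26e-12, and adjusted p = 0.056 with an estimated correlation), with EXO1 at -1.26 (SE 0.12). Senescence-associated secretory genes rose in 12 of 27 cases and fell in 3 (camera adjusted p = 7.43e-07, and adjusted p = 0.056 with an estimated correlation). Immediate early genes rose in 15 of 26 and fell in 2 (camera adjusted p = 2.4e-06, and adjusted p = 0.056 with an estimated correlation). Basal genes rose in 14 of 25 and fell in 6 (camera adjusted p = 0.0101, 0.0572 without control replicate 1, and adjusted p = 0.128 with an estimated correlation). HIF targets rose in 12 of 35 and fell in 3, and the list was not called (camera adjusted p = 0.0503). The edgeR test called 4987 genes against control, 2365 higher and 2622 lower, 967 of them at least 2-fold. A fit of these 6 libraries alone called 2924.

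Against each compound alone the combination differed in few genes. Against D2HG alone 23 genes were called, 5 higher and 18 lower (1186 at an unadjusted p below 0.05, and 67 by DESeq2). DHRS9 was lower with the combination (8.95 ± 1.87 against 20.7 ± 2.93 CPM, log2 difference -1.21, SE 0.17, adjusted p = 0.00203), as were DSC1 (-1.11), KRT75 (-0.86) and TMEM86A (-0.79). The exporter SLC47A1 (0.99), the folate enzyme ALDH1L2 (0.48) and PSAT1 of serine synthesis (0.40) were higher, with adjusted p up to 0.0351. The HIF target list was lower, with 4 of 35 genes called (8 adjusted over the list alone, camera adjusted p = 6.14e-07, and adjusted p = 0.0028 with an estimated correlation). The G2/M list was higher with 0 genes called over all genes and 11 adjusted over the list alone (median 0.24, camera adjusted p = 1.75e-21, and adjusted p = 0.0334 with an estimated correlation). The cholesterol synthesis list was higher with 1 and 6 genes (camera adjusted p = 1.25e-09, and adjusted p = 0.0334 with an estimated correlation). The keratinocyte list was lower with 1 gene and 9 adjusted over the list alone (median -0.60, camera adjusted p = 3.28e-19, and adjusted p = 0.0841 with an estimated correlation). The calls of the 7 genes named above, from DHRS9 to PSAT1, were each lost in at least 1 other fit (up to adjusted p = 0.359, for TMEM86A, without D2HG replicate 3). The count was 4 without D2HG replicate 1 or 2, 3 without D2HG replicate 3, 1 without D2HG+L2HG replicate 2, 11 without D2HG+L2HG replicate 3, 12 in the fit of the 6 libraries alone and 373 without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1 together.

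Against L2HG alone 88 genes were called, 52 higher and 36 lower (1861 at an unadjusted p below 0.05, and 212 by DESeq2). BMP6 was higher with the combination, 14.7 ± 2.4 against 6.17 ± 0.509 CPM (log2 difference 1.25, SE 0.17, adjusted p = 0.000931), as were HRCT1 (1.41), DHRS9 (1.13) and the decoy receptor IL13RA2 (1.08). SULT4A1 (-1.71), the transcription factor gene OSR2 (-1.21), TAGLN (-1.03, SE 0.14, adjusted p = 0.000931) and PYCR1 (-1.02) were lower. Senescence-associated secretory genes were higher, with 2 of 27 called and 8 adjusted over the list alone (median 0.28, camera adjusted p = 4.28e-08, and adjusted p = 0.0459 with an estimated correlation). Immediate early genes were higher too, with 2 of 26 and 9 (camera adjusted p = 4.28e-08, and adjusted p = 0.0458 with an estimated correlation). Apart from BMP6, each of the 8 named calls was lost in the fit of the 6 libraries alone (up to adjusted p = 0.337), which called 2 genes. The count was 418 without D2HG+L2HG replicate 1, 21 and 16 without its replicates 2 and 3, 15, 29 and 161 without L2HG replicates 1, 2 and 3, and 2049 without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1 together.

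Cells with L2HG and vitamin C differed from those with L2HG alone most clearly in genes that HIF induces in hypoxia. HIF targets fell in 24 of 35 cases and rose in 0 (27 adjusted over the list alone, median -0.51, camera adjusted p = 7.6e-29, and adjusted p = 1.44e-06 with an estimated correlation). EGLN3, a HIF prolyl hydroxylase (chromosome 14, 33924227 to 33951074), fell 7.13-fold from 8.42 ± 0.623 CPM (log2 change -2.83, SE 0.19, adjusted p = 1.38e-09), and BNIP3L by 1.00 (SE 0.081), PDK1 by 1.01 (SE 0.085) and lactate dehydrogenase, LDHA, by 1.03 (SE 0.093), from 2420 ± 183 to 1186 ± 48.6 CPM. The hypoxia-induced carbonic anhydrase CA9 (chromosome 9, 35673928 to 35681159) had 90 counts over the 3 L2HG libraries and 2 over the 3 with vitamin C, a ratio of 0.0221 with a 95% counting interval of 0.00264 to 0.0822 (adjusted p = 7.62e-06). NDUFA4L2, another gene of the hypoxic response, fell from 3.26 ± 1.04 to 0.275 ± 0.146 CPM. The epidermal caspase CASP14 fell from 15.5 ± 3.08 to 0.547 ± 0.224 CPM (28.2-fold lower, adjusted p = 2.69e-08). The gelatinase MMP9 fell from 2.10 ± 0.985 to 0.113 ± 0.0385 CPM. The controls lay between for these genes, with 35 counts of CA9, 0.820 ± 0.313 CPM of NDUFA4L2, 3.55 ± 1.90 of CASP14 and 0.535 ± 0.427 of MMP9. Higher with vitamin C were the hair keratin KRT34 (8.2-fold), the cytokine receptor IL1RL1 (4.74-fold), CYGB (4.71-fold) and BEX1 (3.97-fold), each with an adjusted p of 0.000217 or less.

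Collagens and their hydroxylases fell in 16 of 30 cases and rose in 3 with vitamin C (17 and 4 adjusted over the list alone, median -0.35, camera adjusted p = 3.76e-08, and adjusted p = 0.063 with an estimated correlation). LOXL2, a collagen-crosslinking oxidase (chromosome 8, 23296897 to 23404120), went from 38.3 ± 3.63 to 6.76 ± 0.617 CPM (log2 change -2.50, SE 0.14, adjusted p = 6e-11) and P4HA1, a collagen prolyl hydroxylase, fell by 0.61 (SE 0.091). TET and histone demethylases fell in 10 of 28 cases (camera adjusted p = 0.00152, and adjusted p = 0.063 with an estimated correlation), with KDM3A at -0.78 (SE 0.096) and KDM4B at -0.60 (SE 0.095). G2/M genes rose in 21 of 30 cases (28 adjusted over the list alone, median 0.38, camera adjusted p = 1.7e-13, and adjusted p = 0.107 with an estimated correlation). G1/S genes rose in 18 of 30 cases (camera adjusted p = 1.35e-11, and adjusted p = 0.161 with an estimated correlation). Homologous recombination genes rose in 16 of 26 (camera adjusted p = 1.15e-08, and adjusted p = 0.107 with an estimated correlation), with RAD51C at 0.64 (SE 0.10). Keratinocyte differentiation genes fell in 12 of 33 (19 and 1 rise adjusted over the list alone, median -0.65, camera adjusted p = 1.27e-06, and adjusted p = 0.357 with an estimated correlation), with KLK7 at -1.64 (SE 0.20). Interferon response genes rose in 7 of 30 cases and fell in 3 (camera adjusted p = 0.00547, and adjusted p = 0.111 with an estimated correlation), led by IFIT3 at 1.33 (SE 0.20). Immediate early genes fell in 10 of 26 and rose in 1 (camera adjusted p = 0.000333, and adjusted p = 0.107 with an estimated correlation). Histone genes rose in 5 of 37 cases and their list was not called (camera adjusted p = 0.058). Fibroblast markers rose in 4 of 6 cases and fell in 1 (median 0.54, camera adjusted p = 0.000287, and adjusted p = 0.063 with an estimated correlation), with MFAP5 at 1.49 (SE 0.099). The edgeR test called 2744 genes, 1393 higher and 1351 lower. Without L2HG replicate 2, L2HG+vitC replicate 1 or L2HG+vitC replicate 2 it called 1395, 1601 or 1658, and 4529 without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1 together.

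Against the untreated control, the L2HG+vitC cells also had lower HIF targets. They fell in 21 of 35 cases and rose in 0 (22 and 0 adjusted over the list alone, median -0.42, camera adjusted p = 1.71e-20, and adjusted p = 7.22e-06 with an estimated correlation), with EGLN3 at -2.94 (SE 0.19), PDK1 at -0.95 (SE 0.085) and BNIP3 at -1.01 (SE 0.099). LOXL2 was 9.51-fold lower than in the controls (adjusted p = 1.51e-13), DHRS3 6.31-fold and CASP14 6.45-fold. IL1RL1 (chromosome 2, 102311563 to 102352356) was 15.2-fold higher, FAM25A 12.4-fold, KRT24 10.9-fold and DHRS9 10.1-fold. Keratinocyte differentiation genes were higher in 18 of 33 cases (19 and 1 lower adjusted over the list alone, median 0.94, camera adjusted p = 5.76e-17, and adjusted p = 0.112 with an estimated correlation), with the cornified envelope precursor IVL at 145 ± 16.4 against 34.4 ± 13 CPM. Histone genes were lower in 32 of 37 (median -0.83, camera adjusted p = 9.07e-31, and adjusted p = 0.112 with an estimated correlation). G2/M genes were lower in 20 of 30 (median -0.35, camera adjusted p = 7e-13, and adjusted p = 0.112 with an estimated correlation). p53 targets were lower in 10 of 27 cases and higher in 2 (camera adjusted p = 1.54e-05, and adjusted p = 0.0563 with an estimated correlation). TGF-beta and YAP targets were lower in 11 of 24 and higher in 1 (camera adjusted p = 1.09e-05, and adjusted p = 0.284 with an estimated correlation). Collagens were lower in 7 of 30 and higher in 3 (camera adjusted p = 0.00148, and adjusted p = 0.237 with an estimated correlation). Mesenchymal genes were lower in 6 of 19 (camera adjusted p = 0.00293 downward, and adjusted p = 0.167 with an estimated correlation), although their median was 0.0138 and their mean -0.187. The 6 fibroblast markers were higher by camera (adjusted p = 0.000205, and adjusted p = 0.0563 with an estimated correlation) with 1 called over all genes, MFAP5 (1.81, SE 0.10). The edgeR test called 1984 genes, 951 higher and 1033 lower. It called 1281 or 1175 without L2HG+vitC replicate 1 or 2, and 3236 without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1 together.

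**Figure D4:**
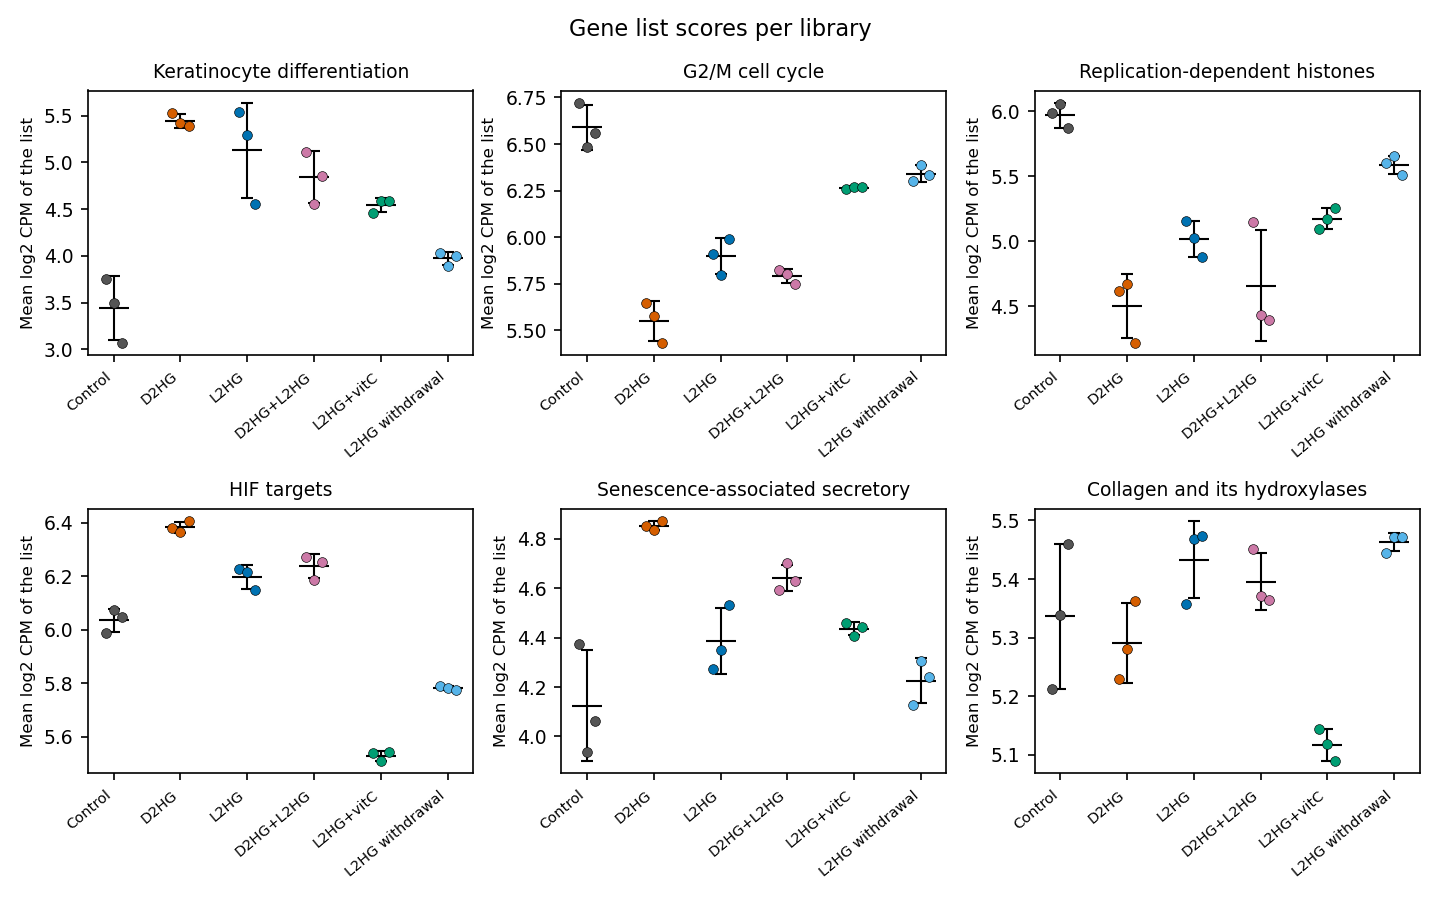
List score (y axis, mean log2 CPM of the list's genes) of 6 gene lists in each of 6 groups (x axis), 1 point per library, with a dash at the mean and bars of 1 SD over 3 libraries. The HIF target score is lowest with L2HG+vitC, and the keratinocyte differentiation score runs from 3.44 in the controls to 5.45 with D2HG.

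After withdrawal of L2HG, most of these changes had moved back towards the control level. Keratinocyte differentiation genes were lower than with L2HG in 25 of 33 cases (27 adjusted over the list alone, median -1.27, camera adjusted p = 3.11e-14, and adjusted p = 0.168 with an estimated correlation), with PI3 at 20.8 ± 1.51 against 104 ± 25 CPM. G2/M genes were higher in 27 of 30 (30 adjusted over the list alone, median 0.44, camera adjusted p = 1.06e-13, and adjusted p = 0.156 with an estimated correlation). G1/S genes were higher in 24 of 30 (camera adjusted p = 1.5e-13, and adjusted p = 0.168 with an estimated correlation). Histones were higher in 19 of 37 (27 adjusted over the list alone, camera adjusted p = 1.89e-10, and adjusted p = 0.342 with an estimated correlation). Homologous recombination genes were higher in 18 of 26 (camera adjusted p = 1.26e-08, and adjusted p = 0.156 with an estimated correlation). HIF targets were lower in 18 of 35 cases and higher in 2 (median -0.32, camera adjusted p = 3.2e-08, and adjusted p = 0.0016 with an estimated correlation). Immediate early genes were lower in 10 of 26 and higher in 2 (camera adjusted p = 0.000147, and adjusted p = 0.156 with an estimated correlation). The chemokine PPBP was 20-fold lower than with L2HG, DHRS9 10.5-fold, CDH16 10.3-fold and CA9 9.91-fold, from 90 counts to 10. CYP1B1, a cytochrome P450 that aryl hydrocarbon receptor ligands induce (chromosome 2, 38067509 to 38076151), was 5.73-fold higher (32.5 ± 1.89 against 5.68 ± 0.956 CPM, adjusted p = 4.61e-12), CYGB 4.88-fold, IL1RL2 4.59-fold and THY1 4.17-fold. The edgeR test called 3982 genes, 1891 higher and 2091 lower.

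Against control, 237 genes were called after withdrawal, 113 higher and 124 lower, 32 of them at least 2-fold. The balance was unstable: 33.2% to 64.6% of the calls were higher with 1 library left out, and 34.3% by DESeq2. The receptor gene IL1RL2 rose 4.74-fold (log2 change 2.24, SE 0.23, adjusted p = 7.29e-06) and CYP1B1 3.08-fold from 10.5 ± 0.485 CPM (1.62, SE 0.12, adjusted p = 3.57e-08), a level above each of the other 5 groups. The epidermal protease inhibitor SPINK5 was 2.98-fold and the uroplakin UPK1B 2.58-fold above control, at 36.3 ± 3.11 and 1.89 ± 0.536 CPM. Their means were higher still with L2HG, 43.0 ± 10.9 and 3.11 ± 0.692 CPM. IL1RL2 stood at 5.54 ± 0.159 CPM after withdrawal, 3.67 ± 0.205 with L2HG+vitC and 1.19 ± 0.448 with L2HG. EGLN3 fell 2.12-fold (adjusted p = 0.000333), NOG, a BMP antagonist, 2.2-fold, MMP1 1.99-fold and FOXQ1 1.94-fold. HIF targets were lower in 10 of 35 cases (17 and 1 higher adjusted over the list alone, median -0.30, camera adjusted p = 4.92e-11, and adjusted p = 0.000246 with an estimated correlation). The G2/M list was lower with 4 of 30 genes called (21 adjusted over the list alone, median -0.29, camera adjusted p = 8.4e-14, and adjusted p = 0.169 with an estimated correlation). The histone list was lower with 3 of 37 (22 and 1 higher adjusted over the list alone, median -0.41, camera adjusted p = 8.4e-14, and adjusted p = 0.333 with an estimated correlation). The keratinocyte list was higher with 3 of 33 (6 and 1 lower adjusted over the list alone, median 0.43, camera adjusted p = 3.59e-07, and adjusted p = 0.333 with an estimated correlation). Ribosomal protein genes were lower (2 of 43 called, 12 adjusted over the list alone, median -0.21, camera adjusted p = 3.28e-10, and adjusted p = 0.333 with an estimated correlation). Their scores overlapped by library, 7.84 to 7.903 after withdrawal against 7.884 to 8.315 in the controls, where replicate 2 was highest. Respiratory chain genes were lower too (2 of 36 called, 8 adjusted over the list alone, camera adjusted p = 1.62e-08, and adjusted p = 0.333 with an estimated correlation). The 6 fibroblast markers were higher by camera (1 called, 2 adjusted over the list alone, median 0.22, adjusted p = 0.00653, 0.103 without control replicate 2, and adjusted p = 0.169 with an estimated correlation). Their score was 3.09 ± 0.0197 after withdrawal, 2.72 ± 0.256 in the controls and 2.55 ± 0.26 with L2HG, and MFAP5 was the gene called (0.41, SE 0.11, adjusted p = 0.0464). The calls of NOG, UPK1B, MMP1 and FOXQ1 were lost in some fits (up to adjusted p = 0.167, 0.13, 0.114 and 0.0905). The count was 363, 154 and 394 without control replicates 1, 2 and 3, 61, 65 and 50 without withdrawal replicates 1, 2 and 3, 563 by DESeq2, 815 with no filter, and 947 without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1 together.

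Of the 4177 genes called with L2HG, 1702 (40.7%) moved back significantly when vitamin C was present and 2702 (64.7%) after withdrawal. In 10 simulated data sets in which the L2HG effect stayed, at most 1 and 0 genes did so. In 10 with a full return 3776 and 3805 did so on average. The simulations used here drew genes independently, so they may understate what noise shared by the genes of a library can produce. They also used 1 dispersion per gene for all groups, although the groups differed in spread. Still called against control in the L2HG direction were 1236 genes (29.6%) with vitamin C and 118 (2.82%) after withdrawal, while 34 and 22 were called in the opposite direction. Across genes, which are not independent replicates, the changes against control with D2HG and L2HG correlated at r = 0.854, where simulated groups without any change gave 0.482 because they share the controls. The covariance was 0.281 against 0.0286 in those simulations. Both compounds raised 1620 genes together and lowered 1725, where independent calls would give 363 and 432, and 5 genes were called in opposite directions. The 3 control libraries were not divided between the comparisons, so part of the excess may come from the shared controls.

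D2HGDH encodes the dehydrogenase that oxidises D2HG. Against control, D2HGDH rose with D2HG to 12.8 ± 1.80 CPM (log2 change 0.51, SE 0.18, adjusted p = 0.0252), a call lost in 3 other fits (up to 0.162, without control replicate 1). It rose with L2HG (0.71, SE 0.17, adjusted p = 0.00336) and with both (0.68, SE 0.17, adjusted p = 0.00421). It had 0.092 (SE 0.18) for L2HG+vitC and -0.061 (SE 0.18) after withdrawal, neither called. TET1 fell from 4.02 ± 1.23 CPM with D2HG (-0.92, SE 0.23, adjusted p = 0.00264) and with both (-1.27, SE 0.24, adjusted p = 0.000227). It had -0.47 (adjusted p = 0.113) with L2HG, -0.34 with vitamin C and 0.065 after withdrawal. TET3 rose from 49.0 ± 8.89 CPM with D2HG (0.54, SE 0.11, adjusted p = 0.000318) and with both (0.37, adjusted p = 0.00928, 0.0686 in the fit of these 6 libraries alone). It had 0.20 for L2HG, -0.15 for vitamin C and 0.027 after withdrawal. TET2, at 48.6 ± 4.97 CPM in the controls, was not called in any comparison with control (-0.022, 0.12, -0.11, -0.10 and 0.10 with D2HG, L2HG, both, L2HG+vitC and withdrawal, SE 0.0967 to 0.0981).

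Among the keratins, KRT5 rose from 14670 ± 2460 CPM with D2HG (log2 change 0.47, SE 0.13), L2HG (0.63) and both (0.54), and had 0.38 (adjusted p = 0.0563) with vitamin C and 0.031 after withdrawal. KRT14 rose from 5407 ± 1490 CPM with D2HG (0.48, lost without control replicate 3 at adjusted p = 0.114), L2HG (0.73), both (0.59) and L2HG+vitC (0.50, lost without control replicate 3 at adjusted p = 0.173), and had -0.015 after withdrawal. The luminal keratins KRT8 and KRT18 fell, KRT8 from 43.8 ± 5.09 CPM by 0.71, 0.56 and 0.71 and KRT18 from 110.0 ± 8.04 CPM by 0.83, 0.74 and 0.78 with D2HG, L2HG and both, and with vitamin C they had -0.14 and -0.13. After withdrawal KRT8 stood at -0.41 (adjusted p = 0.0296, lost in 6 other fits, up to 0.142) and KRT18 at -0.018. Of the 25 genes on the luminal list, 9, 5 and 8 were higher and 6, 6 and 5 lower with D2HG, L2HG and both, and the list was not called (camera adjusted p = 0.323, 0.651 and 0.888). The score of the list was 4.59 ± 0.05 with D2HG against 4.14 ± 0.191 in the controls (difference 0.45, 95% interval 0.288 to 0.612), with SLPI, a secreted protease inhibitor, at 464 ± 44.9 against 52.0 ± 17.8 CPM. The score differed from control by 0.156 (-0.0065 to 0.318) with L2HG and 0.236 (0.0738 to 0.398) with both. KRT19, at 25.1 ± 4.93 CPM, rose with both compounds (0.57, adjusted p = 0.0365, 0.198 without D2HG+L2HG replicate 1) and had 0.29, 0.50, 0.46 and -0.10 with D2HG, L2HG, L2HG+vitC and withdrawal. TP63, a basal transcription factor at 326 ± 43 CPM, was not called in any comparison with control (0.015, -0.054, -0.0039, -0.13 and -0.050 with D2HG, L2HG, both, L2HG+vitC and withdrawal, SE 0.082 each). VIM, the mesenchymal filament vimentin, fell from 653 ± 22.2 CPM by 0.84, 0.33, 0.46 and 0.27 with D2HG, L2HG, both and L2HG+vitC, and by 0.27 after withdrawal, a call lost in 7 other fits (up to adjusted p = 0.176).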

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

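The tests of the libraries that stand apart, of a HIF target return towards control and of the number of libraries per group were chosen only after the result was seen.

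The D2HG effect differed between cells with and without L2HG in 2601 genes, by a test of that difference itself (1256 higher, 1345 lower, edgeR). Of these, 2516 were also called in D2HG against control. That change is itself a part of the difference tested, so the overlap and its sign are no separate evidence. The keratinocyte differentiation list had a median difference of -2.25 (camera adjusted p = 2.91e-33, and adjusted p = 0.0431 with an estimated correlation) and G2/M genes 0.934 (camera adjusted p = 5.89e-39, and adjusted p = 0.0195 with an estimated correlation). G1/S genes had 0.689 (camera adjusted p = 2.15e-17) and histones 1.15 (camera adjusted p = 1.55e-25), both with adjusted p = 0.114 with an estimated correlation. DHRS9 differed by -5.27, the amino acid transporter SLC6A14 by -3.81, the protease inhibitor A2ML1 by -3.06 (SE 0.17), MMP10 by -2.38 and ALDH1A3 by 1.52. Of 100 drawn splits, 10 gave as many genes, the real one included, and the highest of the others gave 5425. By the rule written beforehand, a share this large goes with chance. That rule did not sort the splits. The 9 others all kept the D2HG libraries from the control libraries, so they hold the whole D2HG effect on 1 side by construction. Splits that did not gave at most 706. Those mix D2HG with control libraries, which removes that effect and adds spread by construction. Neither kind of split tells whether chance gave the 2601 genes.

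Few genes differed between D2HG+L2HG and D2HG alone, 23 by edgeR and 67 by DESeq2. More spread from D2HG+L2HG replicate 1 was tested as a cause of the low count, and 20 genes were called without it. Without replicates 2 and 3 of that group, 1 and 11 genes were called. A fit with fewer libraries in the group can also lose calls, so added spread from replicate 1 is not decided. With as many libraries, L2HG against D2HG gave 1280 genes, so 3 libraries per group were not too few for any call. That does not decide whether they were too few for small differences between D2HG+L2HG and D2HG. For D2HG+L2HG against D2HG the count was 373 without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1 together. A response near its ceiling with D2HG alone is a possible explanation that was not tested directly. The doses are not given in the sources used here. On principal component 1 the controls lay at -37.5 to -24.3 and the D2HG libraries at 32.9 to 41.0. The combination lay at 24.3 to 28.55, between the L2HG libraries (8.35 to 22.6) and those with D2HG. A ceiling alone would not place the combination below D2HG, so these values argue against it as the whole explanation. They were considered only after the result was seen.

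D2HG+L2HG replicate 1, control replicate 2 and L2HG replicate 3 stood apart from their groups, and explanations were tested for D2HG+L2HG replicate 1 and control replicate 2. A lower share of nuclear RNA may lie behind this, and 7 nuclear RNAs not seen before the test had a median log2 deviation of -0.354 in D2HG+L2HG replicate 1 (range -1.20 to -0.0283) and -0.199 in control replicate 2. More keratinocyte-like differentiation was tested in the same way, with a median of 0.381 in D2HG+L2HG replicate 1 (range -0.626 to 1.27) and 0.0482 in control replicate 2 (range -1.09 to 1.76). Libraries not tested had medians of similar or larger size: for the nuclear RNAs 0.517 in D2HG+L2HG replicate 3 and 0.346 in L2HG replicate 3, and for keratinocyte genes -0.683 and 0.587 in L2HG replicates 3 and 1 and -0.57 and 0.494 in control replicates 3 and 1. Neither explanation is decided, and these medians do not single out the libraries that stand apart.

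HIF targets were lower with L2HG+vitC than with L2HG. A return of an L2HG effect towards control is argued against as the whole cause by the list scores. That of L2HG+vitC was below control by a difference of -0.508 (95% interval -0.578 to -0.438). That of L2HG was above control by 0.160 (0.0906 to 0.230), so a return may be a part of the difference of -0.669 between them. A shift shared with the withdrawal cultures is argued against as the whole cause by a difference from them of -0.254 (-0.324 to -0.184), but they too lay below control, by a difference of -0.254 (-0.324 to -0.185), so a fall below control was also seen without vitamin C. Library scaling is argued against by a median of -0.516 relative to all genes with RLE factors. An effect of vitamin C beyond that fall stays open as a hypothesis, since no condition received vitamin C without L2HG.

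Comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05. In D2HG against control 1 split, the real one, gave as many as 5647 genes, and the highest of the others gave 1. In L2HG against control 1 split gave as many as 4177, and the highest other gave 664 (control replicate 2 with L2HG replicates 1 and 2 against the rest). For D2HG+L2HG, L2HG+vitC and withdrawal against control, L2HG against D2HG, and L2HG+vitC and withdrawal against L2HG, 1 split gave as many genes (4987, 1984, 237, 1280, 2744 and 3982) and the highest other gave 0. For D2HG+L2HG against D2HG, 2 splits gave at least 23 genes, and the highest other gave 110 (D2HG replicates 1 and 2 with D2HG+L2HG replicate 1 against the rest). For D2HG+L2HG against L2HG, 2 splits gave at least 88, and the highest other gave 1892 (D2HG+L2HG replicate 1 with L2HG replicates 1 and 2 against the rest), which points to a structure of the samples other than the groups.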

How the results depend on the processing

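Leaving out 3 libraries together was chosen only after the result was seen, by their distance from their groups, which lowers the residual spread by construction. Of 260 list tests, 259 kept direction and side of the threshold with RLE factors, 258 with a filter of 1 CPM in 3 samples and 161 with an estimated correlation, which ended 99 calls. Of 7134 tests of named genes with 1 library left out, 6482 stayed the same, 564 lost the call, 88 gained one and 0 reversed. With DESeq2 1121 of 1176 stayed the same. The replicate numbers showed no strong pairing of the libraries. Over 45 pairs of the same number, residuals correlated at 0.0167 on average (-0.239 to 0.247, 10 above 0.1). Over 90 pairs of different numbers they correlated at -0.00876 (-0.456 to 0.363, 10 above 0.1). Of 18 libraries, 8 were closest to those of their own number. A weak pairing is not excluded by these values. With the number as a block, 1164 of 1189 gene tests and 256 of 260 list tests were the same, and withdrawal against control had 305 genes. Spike-in scaling was not run.

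With no filter, withdrawal against control had 815 genes, D2HG+L2HG against D2HG 169 and D2HG+L2HG against L2HG 352. With DESeq2 these were 563, 67 and 212. A fit of only the groups compared, with fewer samples, had 2550 for L2HG against control, 2924 for D2HG+L2HG against control, and 12 and 2 for D2HG+L2HG against D2HG and L2HG. For L2HG+vitC and withdrawal against L2HG it had 3310 and 4756, above the 2744 and 3982 with all libraries. Counts thus moved both ways with fewer samples, so the number of samples alone does not explain the changes. Without control replicate 2, L2HG replicate 3 and D2HG+L2HG replicate 1, L2HG+vitC against control had 3236, withdrawal against control 947, L2HG against D2HG 2358, D2HG+L2HG against D2HG 373 and against L2HG 2049, and L2HG+vitC against L2HG 4529. Leaving out 1 library in turn gave 1175 to 2076 genes for L2HG+vitC against control, 50 to 394 for withdrawal against control, 677 to 978 for L2HG against D2HG, 1 to 20 for D2HG+L2HG against D2HG, 15 to 418 for D2HG+L2HG against L2HG and 1395 to 2888 for L2HG+vitC against L2HG. The cause of these differences was not tested.

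Some list medians reversed. The ribosomal protein median for L2HG+vitC against control, -0.113, ran from -0.195 to 0.0151 (without control replicate 2) and was 0.017 without the 3 libraries. The histone median for D2HG+L2HG against D2HG, 0.191, ran from -0.124 (without D2HG+L2HG replicate 1) to 0.338 and was -0.131 without the 3. Without the 3, L2HG against control also had 0.198 for respiratory chain genes (-0.0397 with all libraries) and 0.227 for ribosomal proteins (-0.0208). D2HG+L2HG against L2HG had -0.0408 for citric acid cycle genes (0.07), -0.0569 for respiratory chain genes (0.109) and -0.124 for ribosomal proteins (0.0531). The cause was not tested.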

Other observations

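The test of the share of withdrawal calls was written beforehand, but the margin used to read it was chosen only after the result was seen.

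NRF2 targets moved apart. AKR1C1, a steroid-reducing aldo-keto reductase, rose with D2HG from 7.10 ± 2.36 to 43.9 ± 1.74 CPM, while GCLM, which serves glutathione synthesis, fell from 154 ± 16 to 59.2 ± 1.16 CPM. With L2HG they stood at 27.0 ± 2.39 and 58.3 ± 12.3 CPM. AKR1C1 and AKR1C2 resemble each other, so short reads can be shared and the split between them is uncertain. The list was not called in D2HG against control (8 of 28 higher, 7 lower, camera adjusted p = 0.497). The desaturase genes FADS2 and FADS1 fell with D2HG, FADS2 from 37.0 ± 4.28 to 14.3 ± 0.352 CPM and FADS1 from 22.9 ± 3.04 to 8.59 ± 1.01 CPM. The fatty acid synthesis list was not called (5 of 18 higher, 5 lower, camera adjusted p = 0.191). The amino acid transporter SLC7A5 fell with D2HG from 1512 ± 301 to 808 ± 45.3 CPM, while the ATF4 list had 5 of 34 higher and 9 lower (camera adjusted p = 0.629).

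Among interferon response genes, OASL rose with D2HG from 0.945 ± 0.115 to 8.45 ± 2.32 CPM and IFIT5 fell from 10.4 ± 0.821 to 4.33 ± 0.467 CPM, with 4 of 30 higher and 10 lower and no call of the list (camera adjusted p = 0.194). MFAP5, a microfibril gene on the fibroblast list, stood at 34.4 ± 2.54 CPM with L2HG+vitC against 12.2 ± 0.836 with L2HG. COL1A2, on the same list, rose after withdrawal from 0.177 ± 0.169 to 1.65 ± 0.0617 CPM (adjusted p = 8.31e-05 against L2HG).

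Genes still called after withdrawal may be a remnant of the L2HG effect. Of the 237 calls, 181 (76.4%) had the sign of the L2HG change, 118 were called with L2HG in the same direction and 22 in the opposite one. In 10 simulated sets with a full return the share was 66.7% to 75.5% (SD 2.61), because both comparisons use the same controls. Those sets had 0 calls, so their top genes were used in place of calls. The value exceeds the highest simulated one by less than that SD. The same sets had 0 genes called with L2HG and again in its direction after withdrawal, against 118 observed, but they also held no other change of the withdrawal cultures. Independent calls would give 15.1 genes higher in both comparisons and 18.3 lower in both, against 61 and 57, and 33.2 in opposite directions, against 22. Neither number allows for the shared controls together with a change of the withdrawal cultures themselves, so a remnant is not told from such a change.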
